A study of Drosophila melanogaster with 16 samples.

How the data were processed

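Total RNA of embryos of both sexes was extracted with Trizol and made into libraries with a NuGEN Ovation kit and ribosomal RNA depletion, per the labels' protocols. The maternal driver expresses the RNA interference construct in the germline, per the labels. The submitters' processing notes name TopHat2 2.0.13, HTSeq 0.5.4p3, DESeq and the build dm3, with no role for any of them; the version of DESeq is not given in the sources used here.

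The authors deposited 2 tables, 1 per collection time, each with 15682 genes. Per the file headers they hold a normalized signal (the mean normalized read count over both conditions), the ratio of condition B over condition A, its log2, a p-value and an adjusted p-value. The deposited log2 was the log2 of the deposited fold wherever both were finite, and the adjusted p matched a Benjamini-Hochberg adjustment of the deposited p-value. Neither the headers nor the labels say which genotype is A or B, and the columns were assigned to none. For the same reason 4 columns were not used, the means of condition A and of condition B in each table. No header or label matches them to a group. The depth per library is unknown from the columns used, so no interval or detection limit is given.

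The design fixed beforehand assumed counts per library, and its fallback for comparison tables was used: no test of differential expression of its own, and the authors' calls at an adjusted p under 0.05. Each fixed list was set against the other tested genes that could have been called (those at or above the lowest mean of any called gene) by Fisher's exact test, one-sided each way, with Benjamini-Hochberg adjustment over 52 list tests per time. Of the gene lists, 27 were fixed before the data were examined. The Fisher's exact test and the median log2 of a list used only its members that could have been called. Counts adjusted over a list alone hold tested members that passed in either direction. On simulated calls at 0-2 hr, with 8348 genes as the background, the list test passed an unadjusted threshold of 0.05 for 95 of 100 lists of 20 genes that were each called with a chance of 40%, and for 6 of 100 lists called at the background rate. At 2-4 hr, with 9386 genes as the background, it did so for 85 and 2 of 100. The simulated calls were independent across genes, so this says nothing about lists whose genes vary together, such as the ribosomal protein genes, whose Fisher p can then be too small.

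The planned tests of histone family sums, of X against autosomes per library, of an interaction between genotype and time and of time within the controls are not reported, since they need values per library. Reads per library can be split out of the condition means, and this was done. Its values are left out because no header or label matches those columns to a group, and no test here rests on them. Against the results given here, the split showed 1 library of condition A at each time rich in late-embryo RNA. Without that library the Hox and dorsoventral genes were seen to stay lower at 2-4 hr, by a check written after the data were seen. The ribosomal protein medians were seen to keep their sign when scaled by the sums of the condition means. No value of either is given, so neither is offered as support. Other checks set down before their results also used those columns and are not reported. They concerned younger embryos in condition B, splits of the libraries, and single libraries for the p53 genes. Their outcomes had been seen too, so the outcomes mentioned above are a selection and do not show robustness. The genes named are Clamp; at each time the 12 largest rises and 12 largest falls among called genes with a mean of at least 20; and up to 4 members of each list with the smallest adjusted p. Other members of the neighbouring gene pairs and genes that 2 lists share were named after their values were seen.

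FlyBase IDs were matched to symbols through a gene name table, which named 15002 IDs and left 680 without a symbol. The BDGP6 annotation gave chromosome arms, gene order and exon lengths only, and no coordinates are printed because the build differs. Some list symbols found no ID and were left out. For each ribosomal protein gene with a mean of at least 20, the 5 nearest other genes in log2 exon length and log2 mean, each scaled by its SD, formed the matched set. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. The authors' calls were also taken at an adjusted p under 0.01 or 0.1, with a mean of at least 20, and at least 2-fold.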

Results

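RNA was sequenced from Drosophila melanogaster embryos in which a maternally driven RNA interference line lowers clamp, the gene of a zinc finger protein that binds GA-rich DNA, and from control embryos. The sample titles call the controls MTD control. Each genotype was collected at 0 to 2 hr and at 2 to 4 hr after egg laying, with 4 libraries in each of the 4 groups and 16 in all. The 0-2 hr collection covers the period in which maternal RNA dominates, and the 2-4 hr collection the main activation of the zygotic genome. The values came as 2 comparison tables, 1 per collection, each with 15682 genes, a mean normalized read count over both conditions, the fold of a condition B over a condition A, and the authors' test between them. Neither the headers nor the labels say which genotype is A and which is B. Condition B is the one with less clamp RNA, and the letters are not genotype labels. The columns used give neither the depth of each library nor the spread between replicates. The overall means summed to 14955921 normalized reads at 0-2 hr and 13946624 at 2-4 hr. Nothing says that the libraries came from separate crosses, so the authors' p-values measure only the spread between these libraries.

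The first comparison asks how the targeted gene stood. In the authors' deposited table, clamp RNA had a mean of 1416 over both conditions at 0-2 hr and was 66.0-fold lower in B, a log2 change of -6.04 with a DESeq adjusted p of 2.62e-179. At 2-4 hr the authors' deposited table gave Clamp a mean of 1654, 38.8-fold lower in B. The log2 change was -5.28, with a DESeq adjusted p listed as 0. The RNA of the targeted gene points to B as the RNA interference condition, which no header or label states.

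At 0-2 hr the embryos of condition B carried far more RNA of Xrp1, a stress-induced bZIP factor, of btd, a head gap gene, and of Pvf2, a ligand of the PDGF and VEGF receptor family. The authors' deposited table gave Xrp1 as 49.99-fold higher in B (log2 5.64, mean 4045), btd as 40.6-fold higher (log2 5.34, mean 682) and Pvf2 as 188-fold higher (log2 7.55, mean 237). Among the genes lower in B were kuk, which encodes a nuclear envelope protein of cellularizing embryos, and GstD1, a glutathione S-transferase. The authors' deposited table gave kuk as 16.9-fold lower (log2 -4.08, mean 3480) and GstD1 as 13.8-fold lower (log2 -3.78, mean 4900). In all, the authors' deposited table called 1463 of 13096 tested genes at an adjusted p under 0.05, 728 of them higher and 735 lower in B. Of these, 304 differed at least 2-fold, 190 higher and 114 lower.

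The largest rises at 0-2 hr in the authors' deposited table were those of Cyp6d2 (log2 8.29), Obp56d (log2 8.24), CG13857 (log2 8.07), Pvf2, CG12290 (log2 7.23), y (log2 6.42), Xrp1, CG12224, btd, CG14110, FBgn0028993 and CG13856. The largest falls were those of GILT3 (log2 -6.89), Clamp, CG32512 (log2 -5.79), GILT2 (log2 -5.01), GstD3 (log2 -4.56), CG2187 (log2 -4.32), mirr (log2 -4.10), kuk, Abd-B (log2 -3.94), CG14879, ft (log2 -3.80) and GstD1. The DESeq adjusted p of mirr, Abd-B and ft lay at 0.0460, 0.0467 and 0.0356 in the authors' deposited table, close to the threshold. Their means were low, at 47.0, 39.9 and 100. At this time a library of condition A was also seen to be rich in late-embryo RNA. Among the rises, y is also one of the genotype markers.

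**Figure D1:**
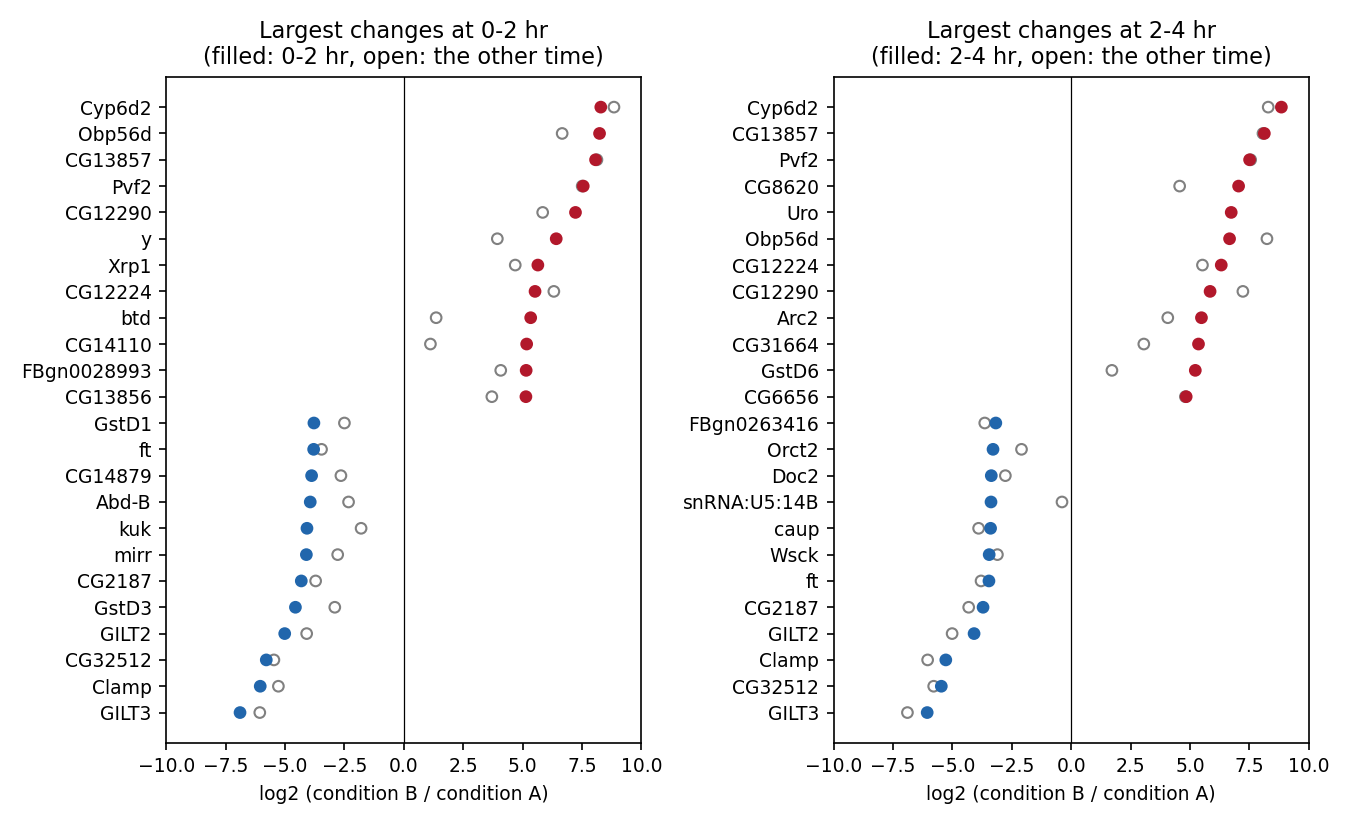
Log2 ratio of the mean normalized count in condition B over condition A for the 12 largest rises and 12 largest falls at each collection time among called genes with a mean of at least 20, as the authors' deposited table gives them. Filled points show the time named in the title and open points the other time; Clamp lies at -6.04 at 0-2 hr and at -5.28 at 2-4 hr, and btd at 5.34 and 1.36.

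Among the gene lists fixed before the data were examined, the list of p53, cell death and DNA damage genes held more genes called higher in B at 0-2 hr than other genes did. The authors' deposited table called 8 of its 19 tested members higher and left 11 uncalled (Fisher's exact test against other tested genes, adjusted p 0.00166 over 52 list tests), and 8 adjusted over the list alone. They included Xrp1, the repair genes Ku80 (2.62-fold, log2 1.39) and Irbp (1.66-fold, log2 0.73), and rad50 (1.61-fold, log2 0.69), in the authors' deposited table. The cell death gene rpr and the p53 target Corp were not called at 0-2 hr, with log2 values of -0.14 and -0.31 in the authors' deposited table. Of the ribosomal protein genes, the authors' deposited table called 46 of 86 lower and left 40 uncalled. Over the 81 that could have been called, the median log2 was -0.37 and the adjusted Fisher's exact p 2.09e-26. Adjusted over the list alone, 72 ribosomal protein genes passed, counted in either direction. Genes matched to them on exon length and mean had a median of -0.16. Cell cycle and replication genes were called lower in 10 and higher in 4 of 36 (adjusted Fisher's exact p 0.0140), and 16 adjusted over the list alone. The cell cycle list no longer passed when calls were taken at an adjusted p under 0.01, and none of these 3 lists passed on calls of at least 2-fold.

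The histone variant genes His2Av and His4r fell at 0-2 hr, by 0.62 and 0.66 on the log2 scale in the authors' deposited table. The U7 snRNP gene Lsm10 fell by 0.86 and FLASH, a histone locus body component, rose by 0.41 there. Neither the histone variant list (2 of 6 lower) nor the histone locus body list (1 higher and 1 lower of 15) passed Fisher's exact test. No call count passed it either, in either direction, for the lists of dosage compensation, early zygotic, segmentation, dorsoventral, Hox, maternal, pole cell, GA-binding, insulator, sex determination, heat shock, eggshell, late muscle, late neuron, late epidermis, hemocyte, yolk and amnioserosa, mitochondrial, small RNA, array histone or genotype marker genes at 0-2 hr. No sperm and testis gene could have been called.

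At 2-4 hr many dorsoventral, segmentation and Hox genes were called lower in B, and many p53 and cell death genes higher. Late-embryo RNA seen in 1 library of condition A leaves a doubt about the patterning genes. So does a possible difference in embryo stage between the conditions, for which no test is given. Marker lists of late embryos had negative medians at the same time, with log2 values of -4.25 for muscle, -2.76 for epidermis, gut and trachea and -1.06 for neurons. In the authors' deposited table rpr, an inducer of apoptosis, was 7.33-fold higher in B (log2 2.87, mean 385) and Corp, a p53 target, 3.09-fold higher (log2 1.63, mean 480.5). There tup, a homeobox gene of the amnioserosa, was 5.75-fold lower (log2 -2.52, mean 103) and Antp, a Hox gene, 5.59-fold lower (log2 -2.48, mean 185) in the authors' deposited table. In all, the authors' deposited table called 2210 of 14245 tested genes, 1051 higher and 1159 lower in B, and 655 of these differed at least 2-fold, 307 higher and 348 lower.

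The largest rises at 2-4 hr in the authors' deposited table were those of Cyp6d2 (log2 8.85), CG13857 (log2 8.13), Pvf2 (log2 7.51), CG8620 (log2 7.05), Uro (log2 6.74), Obp56d (log2 6.67), CG12224, CG12290, Arc2 (log2 5.48), CG31664, GstD6 and CG6656. The largest falls were those of GILT3 (log2 -6.06), CG32512 (log2 -5.47), Clamp, GILT2 (log2 -4.09), CG2187, ft (log2 -3.46), Wsck, caup (log2 -3.39), snRNA:U5:14B, Doc2 (log2 -3.36), Orct2 and FBgn0263416. For caup the DESeq adjusted p was 0.0295 in the authors' deposited table. Another U5 gene, snRNA:U5:34A, went the other way, with a low mean of 9.72 at 0-2 hr. Its log2 there was 3.65 (DESeq adjusted p 0.0135) and, not called, 2.23 at 2-4 hr. The fall of snRNA:U5:14B is therefore not a fall of U5 RNA as a whole.

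The dorsoventral list had 16 of 25 members lower in the authors' deposited table (adjusted Fisher's exact p 9.47e-08), and 18 called adjusted over the list alone. Its members Doc2, tup, scw (3.08-fold lower, log2 -1.62) and tld (2.14-fold lower, log2 -1.10), the last pair in BMP signalling, were among them. The segmentation list had 11 of 21 lower and 1 higher (adjusted Fisher's exact p 0.000137), and 13 adjusted over the list alone. Its Kr (log2 -1.30), ftz (log2 -1.11) and opa (log2 -1.30) were lower and btd (log2 1.36) higher in the authors' deposited table. The Hox list had 5 of 8 lower (adjusted Fisher's exact p 0.00858), and 5 adjusted over the list alone, with Scr (8.13-fold lower), Ubx (6.57-fold lower) and Abd-B (5.01-fold lower) beside Antp in the authors' deposited table. Yolk and amnioserosa genes were lower in 8 and higher in 1 of 11 (adjusted Fisher's exact p 0.000107), and 11 adjusted over the list alone, but this list is largely the dorsoventral one again. It shares 6 of its 11 members with it, and 5 of its 8 lower calls are the shared genes zen, tup, Doc1, Doc2 and Doc3.

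The late-embryo lists had these medians with few calls. The late-embryo muscle list had a median log2 of -4.25 at 2-4 hr over 15 genes, of which the authors' deposited table (DESeq) called 0, with 1 at an unadjusted p under 0.05. At 0-2 hr its median was -2.85, with 1 of 15 called lower in the authors' deposited table. The late epidermis, gut and trachea list had medians of -3.40 at 0-2 hr and -2.76 at 2-4 hr, with 1 higher and 1 lower at each time. The late neuron list had medians of -2.06 at 0-2 hr, with 1 of 13 called higher, and -1.06 at 2-4 hr, with 2 of 13 called lower, elav and nrv2. At 0-2 hr the Hox list, with 1 of 8 called lower, had a median of -3.34, the dorsoventral list, with 2 of 25, one of -1.42, and the segmentation list, with 1 lower and 1 higher of 21, one of -1.09. At 2-4 hr these medians were nearer to 0, at -2.24, -1.10 and -0.52, and a difference between the times was not tested. Adjusted over each list alone, 5 Hox, 8 dorsoventral and 4 segmentation genes passed at 0-2 hr, counted in either direction. The muscle actin gene Act57B was 29.3-fold lower in B at 2-4 hr (mean 511) with an unadjusted DESeq p of 0.224 in the authors' deposited table, a large ratio that the test between libraries did not pass. In the split of the condition means into libraries, which is left out here, 1 library of condition A at each time was seen to be rich in late-embryo RNA. The lower values of the Hox, dorsoventral and segmentation genes are to be read with that library in mind.

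At 2-4 hr the authors' deposited table called 11 of 19 p53, cell death and DNA damage genes higher and 3 lower in B (adjusted Fisher's exact p 2.77e-05), and 14 adjusted over the list alone. With rpr and Corp went Xrp1 (25.8-fold, log2 4.69) and the caspase gene Dronc (1.52-fold, log2 0.61) in the authors' deposited table. The GA-binding and pioneer factor list had 5 of 7 lower (adjusted Fisher's exact p 0.00501), and 6 adjusted over the list alone, but Clamp, the target, is 1 of the 5. Without Clamp, a setting chosen after seeing the data, 4 of 6 were lower (adjusted Fisher's exact p 0.0201). Without opa as well, which the segmentation list also holds, 3 of 5 were lower and the list did not pass (adjusted Fisher's exact p 0.0729). The pioneer factor gene zld was 1.65-fold lower there (log2 -0.72, mean 18189) and grh 3.72-fold lower (log2 -1.89, mean 677) in the authors' deposited table.

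Of 10 dosage compensation genes, 5 were lower in B at 2-4 hr (adjusted Fisher's exact p 0.0218), and 8 adjusted over the list alone. In the authors' deposited table these included msl-2 (1.93-fold lower, log2 -0.94), Sxl, the switch gene of sex determination (log2 -0.80), mle (log2 -0.52) and Set2 (log2 -0.40). The roX1 RNA did not pass the test there, with a log2 of -0.80 and an adjusted p of 0.0507. Mitochondrially encoded genes were higher in 7 of 15 (adjusted Fisher's exact p 0.00535), and 8 adjusted over the list alone. Maternal transcripts were lower in 11 and higher in 3 of 37 (adjusted Fisher's exact p 0.0218), and 17 adjusted over the list alone. Cell cycle genes were lower in 11 and higher in 3 of 36 (adjusted Fisher's exact p 0.0201), and 14 adjusted over the list alone. The maternal and cell cycle lists share 5 genes, of which stg, CycB and CycB3 were among the lower calls of both at 2-4 hr and 4 at 0-2 hr. Both lists no longer passed on calls at an adjusted p under 0.01, on calls with a mean of at least 20 or on calls of at least 2-fold, and the dosage compensation and mitochondrial lists did not pass on calls of at least 2-fold.

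Histone locus body genes were lower in 5 of 15 at 2-4 hr in the authors' deposited table, nej (log2 -0.84), mxc (log2 -0.68), Spt6 (log2 -0.47) and mute (log2 -0.63) among them. That list did not pass Fisher's exact test after adjustment (0.0812), with 5 adjusted over the list alone, and passed it on calls at an adjusted p under 0.01. Ribosomal protein genes were higher in 16 of 87, with a median log2 of 0.23 (adjusted Fisher's exact p 0.0812). Adjusted over the list alone, 29 passed. Genes matched on exon length and mean had a median of 0.18, against 0.22 for the 80 ribosomal protein genes they were matched to. The ribosomal list passed on calls at an adjusted p under 0.1. Pole cell genes were lower in 5 and higher in 1 of 12 (adjusted Fisher's exact p 0.0504), and 10 adjusted over the list alone, and that list passed on calls at an adjusted p under 0.01 or 0.1. The pole cell list shares 6 of its 12 genes with the maternal list. Of its 5 lower calls, 3 are the shared genes osk, tud and pum, and its 1 higher call is shared too. Early zygotic genes went both ways, 5 higher and 4 lower of 26. In the authors' deposited table sisA was 3.13-fold higher in B (log2 1.65), CG13711 lay at log2 1.43 and nullo at log2 0.51. Among the lower early zygotic genes, run is also in the segmentation list, and zen and SoxN are also in the dorsoventral list. No result given here tests whether the embryos of condition B were younger within the 2-4 hr collection. The lists of histone variant, insulator, sex determination, heat shock, eggshell, late muscle, late neuron, late epidermis, hemocyte, array histone, small RNA and genotype marker genes did not pass Fisher's exact test at 2-4 hr, and no sperm and testis gene could have been called.

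**Figure D2:**
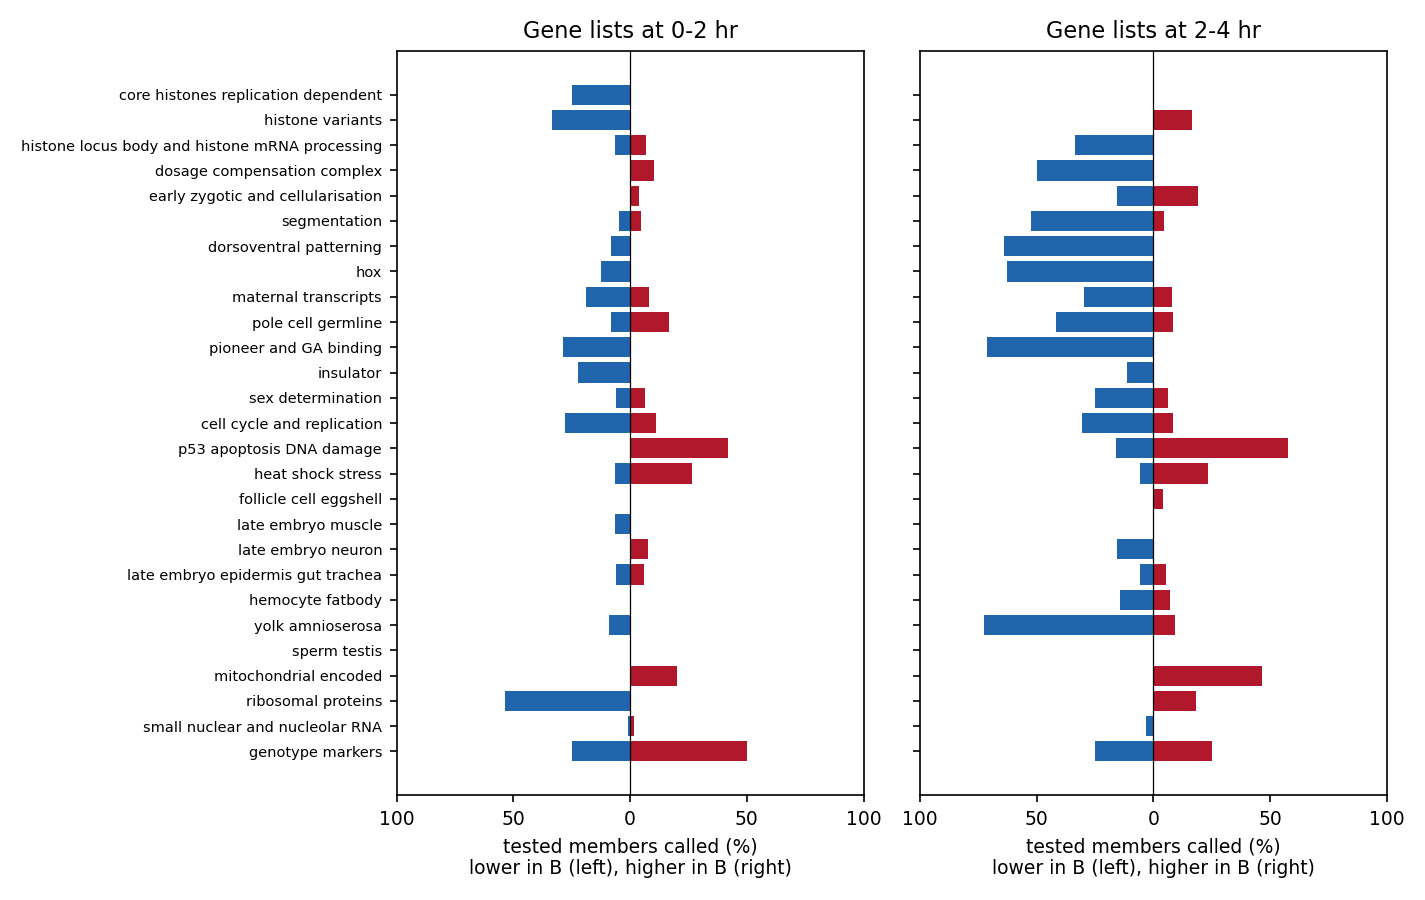
Share of the tested members of each fixed gene list that the authors' deposited table called higher (red, right) or lower (blue, left) in condition B at 0-2 hr and at 2-4 hr, in percent. At 2-4 hr 16 of 25 dorsoventral genes were lower, and at 0-2 hr 46 of 86 ribosomal protein genes were.

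The replication-dependent histone genes of the array are nearly identical copies, so values of single copies are uncertain. Of 111 array genes, 8 were tested at each time. At 0-2 hr the authors' deposited table called 2 of them, both lower in B: His2B:CG17949 (log2 -2.14, adjusted p 1.99e-08) and His2B:CG33868 (log2 -1.79, adjusted p 0.00280). At 2-4 hr the authors' deposited table gave these copies log2 values of -0.35 and -0.99 with adjusted p of 0.383 and 0.0508, and DESeq called 0 of the 8, with 2 at an unadjusted p under 0.05. Whether the change differed between the times was not tested.

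The clamp protein takes part in dosage compensation of the X chromosome, so X-linked genes were set against autosomal ones, without a test, since no value per library was used. At 0-2 hr 1203 X genes with a mean of at least 20 had a median log2 of 0.00058 in the authors' deposited table, and 5409 genes of the large autosomal arms one of -0.0066. At 2-4 hr the medians were -0.040 over 1232 X genes and 0.0091 over 5710 autosomal genes in the authors' deposited table. There 18.0% of the X genes were called lower in B and 11.9% higher, against 14.7% and 13.2% of the autosomal genes. Chromosome 4, which is not among the large arms, had 5.3% of 75 genes called lower and 26.7% higher at 2-4 hr. At 0-2 hr it had 17.5% of 63 genes called lower and 14.3% higher. The embryos were of both sexes, which these values do not separate. The X medians therefore neither show nor exclude a change in dosage compensation.

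Many genes were called at both collection times. The authors' deposited tables called 333 genes higher in B at both, against 59.2 for independent lists, and 209 lower at both, against 66.0. In opposite directions 86 were called, for which no expected count was computed. The expected counts were taken over all 12911 genes tested at both times. These include genes too low to be called, unlike in the list tests, so the expected counts are on the low side. Cyp6d2, Pvf2, Xrp1, GILT2 and CG32512 were among the genes called at both. Across 6939 genes the log2 changes at both times had a Pearson r of 0.80 and a Spearman rho of 0.30, and genes are not independent replicates. These genes included late-embryo genes called at neither time, such as Act57B (log2 -5.97 and -4.87) and Gasp (log2 -6.56 and -5.00). Late-embryo RNA seen in 1 library of condition A at each time may raise both correlations, which was not tested. A difference between the times was not tested for any gene or list, and the tables were normalized separately.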

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

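All settings in this part except those of the GA-binding list were planned before the data were examined. The calls of 0-2 hr numbered 971 at an adjusted p under 0.01 and 304 at 2-fold, and those of 2-4 hr 655 at 2-fold, as stricter limits leave fewer genes; the other counts stayed within 1.5 times. Of the 3 list tests passed at 0-2 hr, 0 passed on calls of at least 2-fold, and of the 10 at 2-4 hr the settings left 6 to 10. Lists that had not passed also did so under a setting: heat shock (higher) at 0.1 at 0-2 hr and at 0.01 and 2-fold at 2-4 hr, and at 2-4 hr histone locus body (lower) at 0.01, pole cell (lower) at 0.01 and 0.1, and ribosomal protein genes (higher) at 0.1; the cause was not tested. The GA-binding list kept its pass at 2-4 hr without Clamp (4 of 6 lower) and lost it without Clamp and opa (3 of 5), with fewer members tested. X minus autosomal genes was 0.066 at 0-2 hr and -0.0154 at 2-4 hr with means, against 0.0072 and -0.049 with medians; the cause was not tested. Clamp passed each threshold, but its deposited value is the same in all, so this says nothing about its stability. Of 371 values of named genes, 28 lost a call at an adjusted p under 0.01 and 87 at 2-fold, and 18 gained one at 0.1. No paired analysis was possible because the columns used carry no replicate numbers. Leave-one-out fits, other count tests and normalizations, filters on low counts, library composition and camera are not reported, since they need values per library, which only the unused columns of condition means could give. A threshold applied to deposited values does not test how a call depends on any 1 library.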

Other observations

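Heat shock and stress genes went higher in part. In the authors' deposited table Hsp23, a small heat shock gene, was 1.95-fold higher in B at 0-2 hr and 3.52-fold higher at 2-4 hr, and the stress-response gene TotA, with a low mean of 9.26 at 0-2 hr, was 34.9-fold and then 63.96-fold higher. The list had 4 higher and 1 lower at each time and did not pass Fisher's exact test after adjustment (0.1495 at 0-2 hr and 0.0812 at 2-4 hr). It passed on calls at an adjusted p under 0.1 at 0-2 hr, and on calls at one under 0.01 or of at least 2-fold at 2-4 hr. Of the genotype markers, y was 15.3-fold higher in B at 2-4 hr in the authors' deposited table, and v had a log2 of 3.60 at 0-2 hr and, not called, of 1.14 at 2-4 hr (DESeq adjusted p 0.570). In the authors' deposited table w was lower in B at both times, with a log2 of -0.37 and -0.52. There sc, with -0.21 and 0.089, was not called at either. A difference in genetic background between the conditions was not tested. For any gene named here, it cannot be told apart from an effect of less clamp RNA.

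Of the ribosomal protein genes, 46 of 86 were called lower in B at 0-2 hr, and 16 of 87 were called higher at 2-4 hr, where the list did not pass its test. The tests of this pattern were set down before their results, and whether the change differed between the times was not tested. The authors' size factors are not excluded by the columns used. With the median gene at 0, the median log2 closest to 0 over both times was 0.23. The median gene already lay at -0.0063 and -0.0078, so this scaling moves little. Scaling by the sums of the condition means was seen to keep the sign at both times. That scaling is left out because no header or label matches those columns to a group. With no size given, it decides nothing. Gene length may contribute and cannot be told apart, nor can it be separated from the mean, which was matched together with it. Genes matched on exon length and mean had a median of -0.16 at 0-2 hr, against -0.37 for the ribosomal protein genes. At 2-4 hr the values were 0.18 against 0.22. The matched genes had lower means (a median of 6591 against 13694 at 0-2 hr), so the match was incomplete. An effect of less clamp RNA was not tested and stays open.

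A count of neighbours was made after adjacent genes were noticed among the largest changes. Of 6582 genes with a mean of at least 20 at both times and a place on a chromosome arm in the annotation used, 61 were called and differed at least 4-fold in the same direction at both, 40 higher and 21 lower in B. They held 7 pairs of neighbouring genes, Arc1 and Arc2, GstE5 and GstE6, CG18547 and CG12224, GstD1 and GstD3, GILT3 and GILT2, CG3457 and Mct1, and CG32512 and CG1503, of which 6 pairs went the same way. Several pairs are members of 1 gene family, and whether 7 is more than chance gives was not tested.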
